A study of Homo sapiens with 8 samples.

How the data were processed

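The libraries were prepared from polyadenylated RNA of tdTomato-positive MDA-MB-231 cells sorted from engineered bone tissues at day 10 after seeding with 5000 cancer cells per tissue, per the labels' protocols. The bone had been cultured for 1 week of stromal cell expansion and 3 weeks of osteogenic maturation. The labels assign 4 samples to ME and 4 to OB. Nothing in the labels says whether the 4 samples of a group came from separate cultures or experiments, so p-values measure the spread between these samples, which may be partly technical.

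The authors deposited a single table of estimated counts, with 30160 gene symbols as rows and 1 column per library. Per the submitters' processing notes, kallisto 0.50.1 and the GRCh38.p14 build were used. How transcript estimates were summed to genes and rounded is not given in the sources used here. The values are whole numbers and differ in total between libraries, as unnormalised counts do, and were rounded again before testing, which changed nothing. Columns were matched to samples by the identifiers in the sample descriptions, and no column was left without a sample. Because kallisto shares reads among transcripts by probability, the counts of near-identical genes such as the HLA genes, and of overlapping or antisense genes, are uncertain. Of the rows, 29896 match a RefSeq gene symbol of GRCh38.p14, from which coordinates were taken, and 9901 are at 0 in every library. COL3A1 is among the rows at 0 although COL1A1 is abundant, so a 0 in this table need not mean that a transcript was absent from the cells.

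Library totals were 15.5, 9.13, 36.6 and 19.0 M in OB replicates 1 to 4 and 29.3, 39.9, 38.6 and 36.7 M in ME replicates 1 to 4. A count of 0 in a library allows up to 3 counts at 95% confidence, which is 0.329 CPM in the shallowest library, OB replicate 2, and 0.0753 CPM in the deepest, ME replicate 2. Such limits cover counting error only, since PCR copies without molecular identifiers are not independent molecules. Low-expressed genes are therefore measured less precisely in OB. The median standard error of the log2 fold change was 0.143, and the biological coefficient of variation was 17.5%.

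Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and the quasi-likelihood F test compared ME with OB without a block. The Benjamini-Hochberg adjusted p threshold was 0.05, two-sided, over 13443 genes. Standard errors were computed as the absolute log2 fold change divided by the square root of F. CPM values use TMM-scaled totals, and log2 CPM uses a prior count of 1. Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 36 lists with at least 5 tested members, out of 38 fixed. Camera compares the genes of a list with all other tested genes. Camera with an estimated correlation per list and fry were run beside it. Fry in its directional form called 0 lists and in its mixed form, which asks for change in either direction, 21. An exact permutation test of the mean log2 CPM of each list over the 70 assignments of labels, chosen later, gave p = 0.0286, the smallest possible, for 3 lists (MHC and antigen presentation, fatty acid synthesis and storage, growth factor receptors and ligands), with a smallest adjusted value of 0.343; adjustment over 36 lists could pass only with at least 21 at that smallest p, so the absence of calls says nothing about the lists. For each list, members were also counted with p adjusted over all genes and adjusted over the list alone. Summed CPM of the 6 lists of other cell types, library totals and numbers of detected genes were compared by exact two-sided permutation tests.

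The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule took, from genes past the threshold with separated groups and at least 5 CPM in the higher group, up to 12 in each direction by fold change. It added up to 4 members of each list with the smallest p, a fixed set of 12 genes (CXCR4, SPP1, IL11, PTHLH, CSF2, CSF3, CXCL8, IL6, JAG1, VCAM1, MKI67 and VEGFA), and the 5 genes with the smallest p past the threshold. With 2 genes past the threshold, the first and last parts named the same 2. COL1A1, COL3A1 and the genes of observed ranks 3 to 12 by p or under GC correction that belong to no list were chosen after their values were seen.

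The gene test was tried on simulated counts drawn from the real means, dispersions and library sizes, with 200 of 13443 genes changed. It recovered 55.2% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 89.4% of those changed 4-fold, with 10 false calls among 159. In the same kind of simulation, 10 of 10 lists of 20 genes shifted 1.2-fold were called and 0 of 10 unshifted lists, with either correlation; simulated genes vary independently within lists, unlike real ones.

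GC content was taken from the longest GENCODE 29 transcript carrying each symbol, for 12993 of the 13443 tested genes (96.7%). In the GC-corrected fit, a loess curve (span 0.5) of each library's deviation from the gene mean of log2 CPM on GC content served as an offset. This correction was tried in this 1 form, after the uncorrected fit had given 2 genes. On counts simulated with the library trends of the real data, this fit recovered 140 of 190 changed genes with 6 false calls, and the uncorrected fit 132 with 4. The simulated dispersions came from the uncorrected fit and already held the variance of the trends, so the gain may be understated. The alternatives fixed before the data were examined were RLE, upper-quartile and total-count scaling, DESeq2 1.42.0, limma-voom, no low-count filter, a minimum mean of 5 CPM, the replicate number as a block, a minimum absolute log2 fold change of 1, leaving out mitochondrial and ribosomal protein genes, and leaving out each library. Added later were thinning to equal depth, the mean log2 CPM of 11 stromal markers as a covariate, the GC correction with and without the block, list means over a fixed set of members, and an adjusted p threshold of 0.1. The relations of 96 genes and 36 lists (without the 11 stromal markers) with that stromal score, and with the log2 summed CPM of the 10 endothelial markers under the low-count filter, were added later too. Values were centred by group, permutation p-values came from all 576 relabelings of libraries within groups, and adjustment was made separately for genes and lists and for each score and measure. Figures were drawn with matplotlib from these results.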

Results

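RNA sequencing measured polyadenylated RNA from MDA-MB-231 cells, an established triple-negative breast cancer line, here carrying a tdTomato reporter. The cancer cells had been grown in engineered human endosteal bone, made by letting bone marrow stromal cells mature into osteoblasts on decellularized bovine bone, and were sorted on tdTomato at day 10. In the group called ME the bone had also received mesenchymal stem cells and endothelial cells, whereas in the group called OB osteoblasts were the only bone cells named. Each group held 4 libraries. The protocol text attached to all 8 samples lists mesenchymal, endothelial and blood progenitor cells in the seeding mix, so the labels do not settle which of these the OB tissues received. Library totals ranged from 9.13 to 36.6 M estimated counts in OB and from 29.3 to 39.9 M in ME. The mean was 36.1 ± 4.74 M in ME and 20.1 ± 11.7 M in OB (SD, n = 4 each), a ratio of 1.80 (exact permutation test, two-sided, p = 0.0571). Genes with at least 1 count numbered 16743 ± 206 in ME and 16123 ± 628 in OB (SD, n = 4 each, exact permutation p = 0.143). Correlations of log2 CPM between libraries lay between 0.956 and 0.980, with a mean of 0.968 within OB, 0.976 within ME and 0.970 between the groups.

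The comparison asked how the transcriptome of the cancer cells differed between bone with added stromal and endothelial cells and bone with osteoblasts. ADGRF1, an adhesion G protein-coupled receptor, was lower in ME, at 7.85 ± 1.54 CPM against 24.1 ± 5.28 CPM in OB (SD, n = 4 libraries per group here and throughout), which is 3.05-fold higher in OB. Its log2 fold change was −1.61 (SE 0.18, edgeR quasi-likelihood adjusted p = 0.00432), and all 4 ME values lay below all 4 OB values. Centred by group, ADGRF1 followed the log2 sum of 10 endothelial markers under the low-count filter at r = 0.775 and rho = 0.810 (permutation p = 0.0469 and 0.0347, adjusted 0.409 and 0.367 over 96 genes). Its r without ME replicate 2 and OB replicate 1 was 0.563. Between the groups the 2 went opposite ways, with the endothelial sum at 2.74 ± 1.54 CPM in ME and 0.673 ± 0.539 CPM in OB. That sum rests on only 1, 11, 14 and 20 counts in OB replicates 1 to 4, so it is imprecise there. TGFBI, a secreted matrix protein induced by TGF-beta, was higher in ME, at 240 ± 8.00 CPM against 147 ± 16.3 CPM, with a log2 fold change of 0.71 (SE 0.09, adjusted p = 0.0125) and no overlap between the groups. ADGRF1 lies on chromosome 6 from 46997708 to 47042332 and TGFBI on chromosome 5 from 136028988 to 136063818 (GRCh38.p14). Both are annotated as protein-coding, and the values are gene totals over their transcripts. Of 13443 genes tested, these 2 passed an adjusted p of 0.05, 1 in each direction, and 1087 had an unadjusted p under 0.05 (538 higher and 549 lower in ME, against 672 if genes were independent and unchanged). The groups did not overlap in 649 genes, 4.83% of those tested, where chance gives 2.86%. Neither number stood out, since 3 of the 35 ways to split the 8 libraries, the real 1 included, reached each, with 1668 and 1062 genes in the highest other splits. The count of calls moved with the method: DESeq2 called 147 genes, and a correction for library-specific trends with GC content, chosen after the data were examined, called 33 (21 higher and 12 lower in ME), or 2 to 30 with 1 library left out. It also moved with single libraries, since 17 genes passed without OB replicate 3, while TGFBI missed the threshold without OB replicate 1 (adjusted p = 0.0549), ME replicate 1 (0.0573), ME replicate 2 (0.0752) or ME replicate 4 (0.0634).

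**Figure D1:**
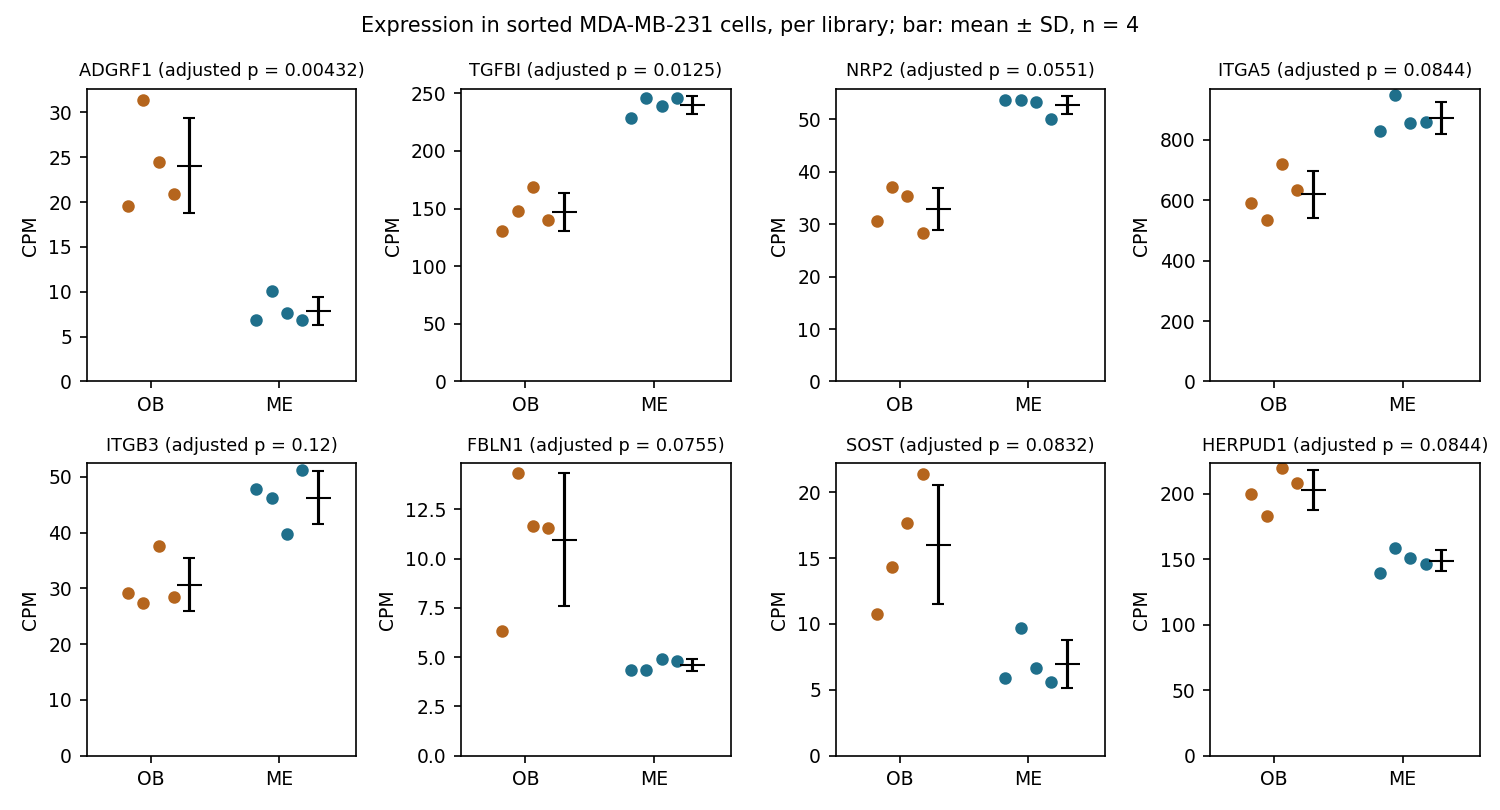
CPM (vertical axis, from 0) of 8 genes in each of the 4 OB and 4 ME libraries, as points, with the mean and SD of each group as a bar beside them. ADGRF1 and TGFBI, the 2 genes past the threshold, show no overlap between groups, with TGFBI at 229 to 246 CPM in ME and 130 to 169 CPM in OB. The other 6 genes are separated too, with adjusted p-values from 0.0551 to 0.120.

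Genes of hypoxia and glycolysis were called higher in ME as a group, although the libraries of the groups overlapped. Of 26 tested members, 23 had a positive log2 fold change, the list mean was 0.19 (a change of 13.8%), and the list was called by camera (adjusted p = 6.83e-06). With an estimated correlation the call was lost (adjusted p = 0.706). By the list's mean log2 CPM, OB replicate 1 (8.16) lay above all ME libraries (8.01 to 8.10), OB replicate 3 was at 8.01, and OB replicates 2 and 4 were at 7.59 and 7.57. The mean log2 fold change was 0.30 without OB replicate 1, 0.11 without OB replicate 2 or OB replicate 4, and 0.095 with the stromal marker score as a covariate. None of the members passed over all genes, and 5 passed, all higher, when adjusted over the list alone. SLC2A1 and SLC2A3, which carry glucose into the cell, stood at 891 ± 25.5 against 716 ± 103 CPM and at 297 ± 26.5 against 235 ± 33.6 CPM. PFKFB3, a stimulator of glycolysis, stood at 128 ± 13.9 against 90.2 ± 21.2 CPM and ADM, which encodes the vasodilator adrenomedullin, at 88.7 ± 8.03 against 70.1 ± 5.12 CPM. VEGFA, the main endothelial growth factor, measured 999 ± 56.6 against 874 ± 107 CPM (log2 fold change 0.19, SE 0.09, adjusted p = 0.630). Fatty acid synthesis and storage was called higher as well, with a mean of 0.16 over 19 members (13 positive, camera adjusted p = 0.00928, adjusted p = 0.522 with an estimated correlation) and 1 member higher when adjusted over the list alone. That member was DGAT2, an enzyme of triglyceride synthesis, at 9.30 ± 1.04 against 4.70 ± 1.51 CPM. This second call was lost without OB replicate 2 (mean 0.092, adjusted p = 0.135), without ME replicate 2 (mean 0.13, adjusted p = 0.0716) and with the stromal covariate (mean 0.14, adjusted p = 0.0841).

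Laminins, type IV collagen and integrins made up the list with the most separate movers. In basement membrane and integrins, 8 of 24 members were higher and 2 lower when adjusted over the list alone, although none passed over all genes. Camera called the list higher in ME (camera adjusted p = 0.00102, adjusted p = 0.706 with an estimated correlation), with a mean log2 fold change of only 0.007 and a median of 0.12, because a few low-expressed members had strongly negative values. ITGA5, the fibronectin receptor subunit, stood at 873 ± 52.0 against 620 ± 78.0 CPM (log2 fold change 0.49, SE 0.09, adjusted p = 0.0844). ITGB3, a subunit of the vitronectin receptor, stood at 46.3 ± 4.77 against 30.6 ± 4.74 CPM (0.59, SE 0.13, adjusted p = 0.120). COL4A2 stood at 118 ± 23.4 against 75.1 ± 10.8 CPM (adjusted p = 0.120). LAMC2, a laminin chain, stood at 796 ± 92.5 against 607 ± 89.7 CPM. The list's mean log2 CPM was not higher in ME, at 5.958 against 5.959 in OB. Without ME replicate 2 the call was lost (adjusted p = 0.0672) and the mean log2 fold change was −0.11, and without OB replicate 1 that mean was −0.069 with the call kept. Scaling alone moved the mean past 0, to −0.001 with RLE and −0.006 with total counts, and it was −0.0001 without OB replicate 4, each with the list still called. ME replicate 2 also held the most counts (193) of the 10 endothelial markers under the low-count filter. Centred by group, the list mean followed the log2 sum of those markers at r = 0.781 and rho = 0.810 (permutation p = 0.0469 and 0.0417, adjusted 0.281 and 0.453 over 36 lists). Its r without ME replicate 2 and OB replicate 1 was 0.501. COL4A2 was highest in ME replicate 2 too (144 CPM), but over the 8 libraries it gave r = 0.501 and rho = 0.524 (permutation p = 0.260 and 0.234, adjusted 0.667 and 0.689 over 96 genes), and r = 0.202 without the same libraries.

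Related matrix lists were not called with all 8 libraries. Fibrillar collagens and matrix had 2 of 23 members higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.157), among them TNC, tenascin C, at 535 ± 115 against 346 ± 56.1 CPM and LOXL2, a collagen cross-linking enzyme, at 370 ± 36.4 against 278 ± 25.7 CPM. The mean of that list was −0.031. It was called higher without OB replicate 2 (mean 0.089, adjusted p = 0.00836), without ME replicate 1 (0.059, adjusted p = 0.0202) and with the stromal covariate (0.30, adjusted p = 1.24e-11). The stromal score holds COL1A1, COL1A2, DCN, LUM and POSTN, which are also members of this list, so the last call is partly built in. The list had a mean of −0.18 without OB replicate 1 and −0.14 without ME replicate 3. Leaving out stromal markers, its group-centred mean followed the stromal score at r = 0.941 and rho = 0.905 (permutation p = 0.00868 and 0.0156, adjusted 0.146 and 0.281 over 36 lists). Its r without OB replicate 1 and ME replicate 1 was 0.636. Matrix proteases and inhibitors had 2 of 21 higher and 1 lower (camera adjusted p = 0.498), with TIMP3, an inhibitor of metalloproteinases, at 623 ± 51.7 against 470 ± 20.8 CPM and PLAU, urokinase, at 1616 ± 38.3 against 1257 ± 198 CPM. Epithelial-mesenchymal transition had 1 of 18 higher and 2 lower (camera adjusted p = 0.685): SNAI1, a repressor of epithelial genes, stood at 8.25 ± 1.22 against 4.59 ± 1.13 CPM, CDH11 at 48.7 ± 4.76 against 70.2 ± 5.26 CPM and PRRX1 at 1.20 ± 0.45 against 3.86 ± 2.16 CPM. Among angiogenic factors 3 of 19 were higher and 1 lower (camera adjusted p = 0.0716). NRP2, a neuropilin receptor for semaphorins and VEGF-C, stood at 52.7 ± 1.77 against 32.9 ± 4.03 CPM (log2 fold change 0.68, SE 0.11, adjusted p = 0.0551) and PGF, placental growth factor, at 10.9 ± 0.553 against 5.86 ± 1.35 CPM. EDN1, endothelin 1, stood at 9.85 ± 1.83 against 16.5 ± 1.64 CPM. TGFBI was the only 1 of the 25 TGF-beta targets past either adjustment (camera adjusted p = 0.862).

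The MHC and antigen presentation list was called lower in ME with the preset correlation only. It had 12 of 15 members with a negative log2 fold change and a mean of −0.22 (camera adjusted p = 0.00462, adjusted p = 0.358 with an estimated correlation). Adjusted over the list alone, 3 members were lower and 1 higher, and over all genes none passed. B2M, the light chain of MHC class I, stood at 2012 ± 182 against 2509 ± 240 CPM, PSMB9, an immunoproteasome subunit, at 9.55 ± 1.16 against 15.7 ± 2.91 CPM, and TAP2, a peptide transporter, in the other direction at 35 ± 6.17 against 26.2 ± 1.85 CPM. HLA genes share near-identical sequence, so their own totals are uncertain. Centred by group, the MHC list gave r = 0.842 and rho = 0.619 with the stromal score (permutation p = 0.0347 and 0.153, adjusted 0.208 and 0.540 over 36 lists). That relation rests on OB replicate 1 and ME replicate 1, since r was −0.066 without them. Its member HLA-DRB1 gave r = 0.896 and rho = 0.929 (permutation p = 0.0104 each, adjusted 0.125 each over 96 genes), and r = 0.833 without those libraries. Interferon-stimulated genes had 20 of 25 members with a negative log2 fold change and a mean of −0.15 (camera adjusted p = 0.00626, adjusted p = 0.830 with an estimated correlation), with no member past the threshold over all genes or adjusted over the list alone. IFI6 stood at 315 ± 53.1 against 394 ± 29.5 CPM and OAS2 at 151 ± 25.4 against 185 ± 31.0 CPM. That call was lost without ME replicate 1 (mean −0.042, adjusted p = 0.642) and without OB replicate 3 (−0.063, 0.438), and with the stromal marker score as a covariate (−0.017, 0.876), while without ME replicate 4 the mean was −0.28. The list of inflammatory cytokines and NF-kB targets was not called (mean −0.060, camera adjusted p = 0.194). It was called lower without OB replicate 4 (−0.13, adjusted p = 0.0411) or ME replicate 4 (−0.22, adjusted p = 0.000800). The list had a mean of 0.011 without ME replicate 1, −0.0098 without OB replicate 3 and −0.013 without OB replicate 2. It had 1 of 23 members lower when adjusted over the list alone, the apoptosis inhibitor BIRC3, at 33.5 ± 3.85 against 58.6 ± 16.8 CPM.

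Further lists were called lower in ME. Growth factor receptors and ligands had a mean of −0.28 over 20 members (camera adjusted p = 0.0145, adjusted p = 0.358 with an estimated correlation), with 4 lower and 1 higher when adjusted over the list alone. Among the lower members EREG, the EGF receptor ligand epiregulin, stood at 71.3 ± 12.6 against 99.8 ± 9.14 CPM. The others were the IGF-binding proteins IGFBP4 at 1546 ± 113 against 1870 ± 156 CPM, IGFBP5 at 2.24 ± 0.749 against 5.64 ± 2.49 CPM and IGFBP7 at 337 ± 30.4 against 416 ± 25.1 CPM. Wnt ligands, inhibitors and targets had a mean of −0.45 over 13 members (camera adjusted p = 0.0102, adjusted p = 0.429 with an estimated correlation) and 1 lower member when adjusted over the list alone, the Wnt inhibitor SFRP1, at 0.187 ± 0.115 against 1.05 ± 0.225 CPM. Leaving out stromal markers, the group-centred mean of the Wnt list followed the stromal score at r = 0.981 and rho = 0.976 (permutation p = 0.00174 each, the smallest possible, adjusted 0.0625 each over 36 lists). Its r without OB replicate 1 and ME replicate 1 was 0.972. A single list at the smallest possible p adjusts to 0.0625, so the Wnt list could not pass this adjustment alone. The growth factor list followed the stromal score at r = 0.882 and rho = 0.833 (permutation p = 0.0122 and 0.0260, adjusted 0.146 and 0.312). Its r without those libraries was 0.697. Cell cycle arrest and dormancy had a mean of −0.16 over 17 members (camera adjusted p = 0.0338, adjusted p = 0.429 with an estimated correlation) and 1 lower member, GADD45A, at 105 ± 6.53 against 131 ± 8.90 CPM. CDKN1A, the cyclin-dependent kinase inhibitor p21, stood at 568 ± 15.3 against 648 ± 43.3 CPM. With the stromal marker score as a covariate none of these 3 lists was called (means −0.18, −0.22 and −0.078, adjusted p = 0.0911, 0.343 and 0.0821, in that order). After thinning to equal depth the Wnt call (mean −0.29 over 10 members, adjusted p = 0.0879) and the arrest call (0.0774) were lost, and the growth factor mean was −0.18 over 18 members (0.0482). Without OB replicate 3 the 3 means were −0.27, −0.41 and −0.11, and the adjusted p-values were 0.107, 0.106 and 0.247. Without ME replicate 1 they were −0.24, −0.42 and −0.13, with adjusted p-values of 0.0694, 0.0519 and 0.0923. The arrest list also missed without OB replicate 1 (mean −0.16, adjusted p = 0.0917) and ME replicate 4 (−0.14, adjusted p = 0.0637).

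Proliferation genes did not differ beyond the spread between libraries. G1/S and DNA replication had a mean log2 fold change of 0.006 over 22 members and G2/M and mitosis of −0.018 over 22, with no member of either past the threshold when adjusted over the list alone (camera adjusted p = 0.852 for each). MKI67, a marker of cycling cells, measured 150 ± 14.7 CPM in ME and 148 ± 18.7 CPM in OB (log2 fold change 0.02, SE 0.11, adjusted p = 0.984). The epithelial cancer cell markers had a mean of 0.03 over 13 members and no member past the threshold (camera adjusted p = 0.685).

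**Figure D2:**
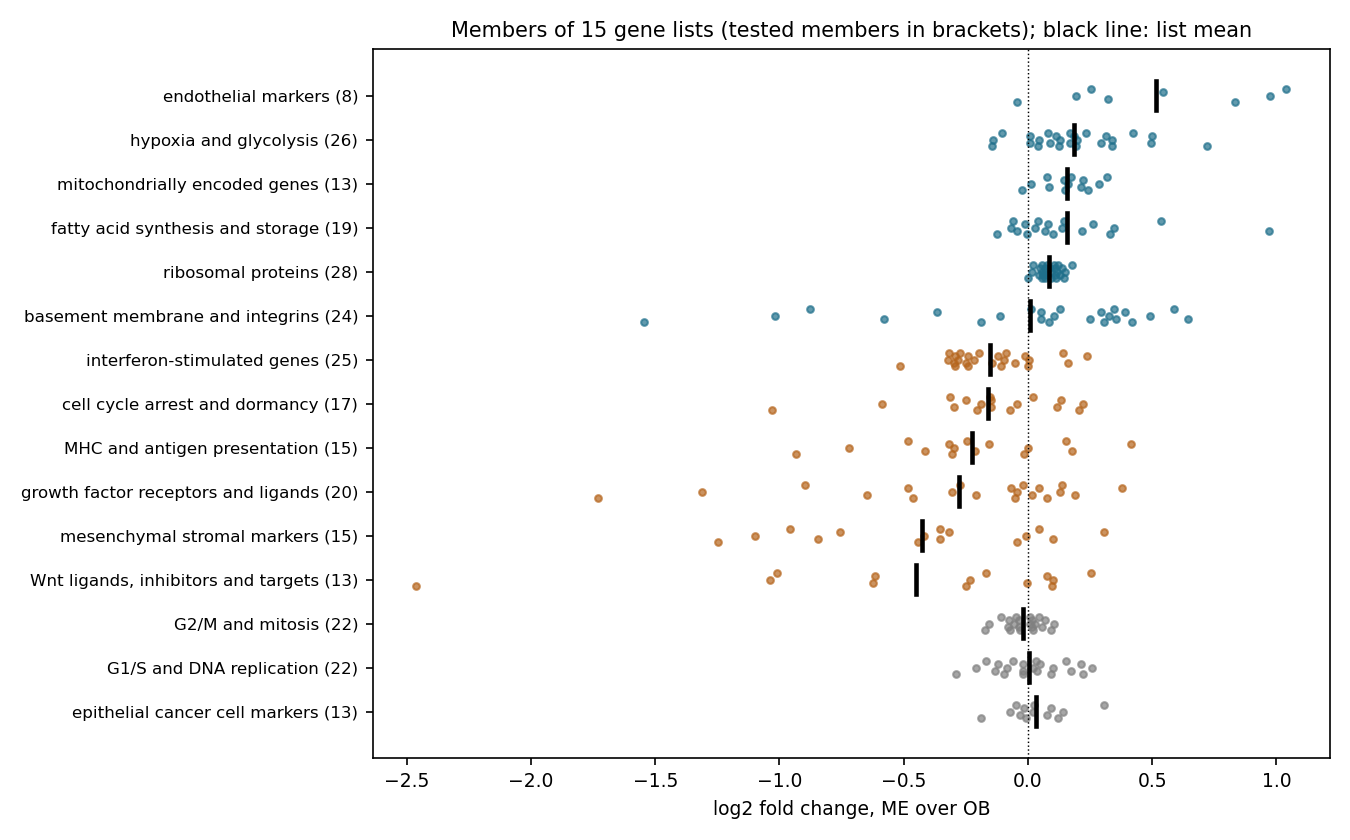
Log2 fold change of ME over OB (horizontal axis) for each tested member, as points, of the 12 gene lists called with a preset correlation, in blue where called higher in ME and brown where lower, and of 3 lists not called, in grey. Black lines mark list means, which run from 0.52 for endothelial markers to −0.45 for the Wnt list, while the mean of the G2/M list lies at −0.018.

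Ribosomal proteins and mitochondrially encoded genes were also called higher, by small amounts that varied with single libraries. All 28 ribosomal protein members had a positive log2 fold change, with a mean of 0.09 (camera adjusted p = 0.0118, adjusted p = 0.874 with an estimated correlation), and 12 of 13 mitochondrial members did, with a mean of 0.16 (camera adjusted p = 0.0241, adjusted p = 0.847 with an estimated correlation). No member passed when adjusted over the list alone. RPLP0 stood at 1025 ± 101 against 927 ± 157 CPM and MT-CO3 at 384 ± 50.1 against 308 ± 96.6 CPM. The mitochondrial mean was −0.036 without OB replicate 1, 0.033 without ME replicate 2 (adjusted p = 0.352), 0.31 without OB replicate 2, 0.27 without OB replicate 4 and 0.43 with the stromal covariate, and the call was also lost without OB replicate 3 (0.183). The ribosomal call was lost without any 1 of OB replicates 1, 2 and 3 (adjusted p = 0.144, 0.190 and 0.341) or ME replicates 1 and 4 (0.0548 and 0.427). Its mean ran from 0.033 without ME replicate 4 to 0.21 without OB replicate 4, with 0.053, 0.043 and 0.047 without OB replicates 1, 2 and 3 and 0.15 without ME replicate 2. OB replicate 4 had the highest ribosomal mean log2 CPM of all libraries, 8.97 against 8.51 to 8.55 in the other OB libraries.

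Genes known for a part in bone metastasis or in support of blood cells showed mixed values. Bone metastasis and osteolysis factors had 1 of 20 members higher, ITGB3, and 1 lower, the collagen-degrading protease CTSK at 13.8 ± 4.54 against 27.4 ± 9.83 CPM, when adjusted over the list alone (camera adjusted p = 0.741). Centred by group, log2 CPM of CTSK followed the stromal score at r = 0.989 and rho = 0.952 (permutation p = 0.00174 each, the smallest possible, adjusted 0.0417 and 0.0556 over 96 genes). Its r without OB replicate 1 and ME replicate 1 was 0.966. The 96 genes included markers of the stromal score itself, which follow it by construction. The adjusted value for the r of CTSK rests partly on their small p-values. Haematopoietic niche factors had 1 of 16 lower, BMP4, a bone morphogenetic protein, at 174 ± 17.5 against 232 ± 35.9 CPM (camera adjusted p = 0.403). None of the genes fixed beforehand for their role in bone metastasis passed. SPP1, osteopontin, stood at 8.23 ± 0.803 against 5.97 ± 1.00 CPM (adjusted p = 0.522), CXCL8 at 320 ± 49.0 against 396 ± 53.2 CPM (0.509), CSF3 at 10.4 ± 2.67 against 13.7 ± 0.809 CPM (0.573) and CSF2 at 157 ± 47.1 against 177 ± 21.3 CPM (0.839). IL6 measured 235 ± 49.7 against 251 ± 40.2 CPM (adjusted p = 0.917), IL11 6.43 ± 1.20 against 6.62 ± 1.10 CPM (0.982), PTHLH 5.17 ± 1.04 against 4.48 ± 1.46 CPM (0.889), JAG1 194 ± 21.6 against 182 ± 21.2 CPM (0.876) and VCAM1 2.80 ± 1.61 against 4.66 ± 2.31 CPM (0.731). CXCR4 had too few counts to be tested, at 0.148 ± 0.184 CPM in ME and 0 in OB, where 3 counts correspond to between 0.0820 and 0.329 CPM in a library.

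Markers of other cell types were read in the sorted cells because the gate could let such cells through. Mesenchymal stromal markers had 12 of 15 tested members with a negative log2 fold change and a mean of −0.43 (camera adjusted p = 0.00231, adjusted p = 0.780 with an estimated correlation), and 4 were lower when adjusted over the list alone. These were FBLN1 at 4.60 ± 0.309 against 11.0 ± 3.36 CPM, DCN at 21.0 ± 7.08 against 45.1 ± 21.6 CPM, LUM at 22.4 ± 7.91 against 40.5 ± 15.4 CPM and THY1 at 8.32 ± 2.74 against 16.2 ± 6.98 CPM. COL1A1 and COL3A1 were chosen for mention after their values were seen: COL1A1 measured 310 ± 127 CPM in ME and 312 ± 154 CPM in OB, and COL3A1 was listed at 0 in every library. The list's call was lost without OB replicate 2 (mean −0.22, adjusted p = 0.135) and OB replicate 3 (0.0930), and the mean was −0.64 without OB replicate 1. Endothelial markers were called higher in ME, with a mean of 0.52 over 8 tested members of 18 (camera adjusted p = 0.00725, adjusted p = 0.358 with an estimated correlation), and PECAM1 was the member that passed when adjusted over the list alone, at 7.01 ± 1.34 against 3.86 ± 1.15 CPM. The endothelial mean was 0.92, 1.08, 0.81 and 0.99 without OB replicates 1 to 4 and 1.07 without ME replicate 1, where 9 or 10 members passed the count filter, but 0.42 to 0.69 over the same 8 members with any 1 library left out. It was 0.78 with the stromal covariate. After thinning, 4 members remained, too few to test. The 10 endothelial markers under the low-count filter were also compared with PECAM1, centred by group. Their log2 sum gave r = −0.689 and rho = −0.571 (permutation p = 0.0885 and 0.182, adjusted 0.529 and 0.689 over 96 genes). PECAM1 was highest in ME replicate 4, where the summed CPM of those markers was lowest in ME (1.48 CPM) and VWF had 0 counts. Osteoblast markers had 1 of 7 tested members lower, SOST, which encodes the Wnt inhibitor sclerostin, at 6.96 ± 1.85 against 16.0 ± 4.54 CPM (list mean −0.28, camera adjusted p = 0.0591). That list was called lower without OB replicate 1 (−0.41, adjusted p = 0.00534), ME replicate 2 (−0.37, adjusted p = 0.0267) or ME replicate 4 (−0.35, adjusted p = 0.0438) and with GC correction (−0.28, adjusted p = 0.0380). Its mean was −0.13 without OB replicate 4 and −0.17 without ME replicate 1, without a call. Haematopoietic markers had 1 of 8 higher, SPI1 at 0.397 ± 0.150 against 0.0739 ± 0.0507 CPM, and 1 lower, SRGN at 18.3 ± 2.02 against 25.9 ± 6.69 CPM (camera adjusted p = 0.928). The OB mean of SPI1 lay below the 0.0820 to 0.329 CPM that 3 counts make in an OB library. Its OB values, and relations that use them, are therefore imprecise. Centred by group, SPI1 followed the stromal score at r = 0.906 and rho = 0.810 (permutation p = 0.0243 and 0.0347, adjusted 0.212 and 0.333 over 96 genes), and at r = 0.697 without OB replicate 1 and ME replicate 1. In the same way SOST followed the endothelial sum at r = 0.786 and rho = 0.833 (permutation p = 0.0417 and 0.0295, adjusted 0.400 and 0.367), and at r = 0.532 without ME replicate 2 and OB replicate 1.

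Summed over each list, none of the 6 kinds of marker passed after adjustment (exact permutation tests, two-sided, 70 assignments, smallest possible p = 0.0286), but with 6 lists at least 4 would have to reach that smallest p before any could pass. Endothelial markers summed to 125 ± 1.86 against 106 ± 8.11 CPM, without overlap (exact permutation p = 0.0286, adjusted 0.114). The 10 members under the low-count filter, VWF, TIE1 and FLT1 among them, gave 2.74 ± 1.54 and 0.673 ± 0.539 CPM of this. ROBO4 (42.6 ± 4.67 against 33.9 ± 5.15 CPM) and EGFL7 (39.1 ± 5.17 against 34.3 ± 4.31 CPM) gave more. Both were present in every library, and their groups overlapped. The sum therefore cannot tell whether endothelial cells passed the gate. Osteoblast markers summed to 82.0 ± 4.59 against 98.4 ± 8.47 CPM (exact permutation p = 0.0571, adjusted 0.114). Mesenchymal markers summed to 1527 ± 279 against 1699 ± 477 CPM (exact permutation p = 0.657) and haematopoietic markers to 509 ± 34.2 against 510 ± 63.6 CPM (exact permutation p = 1). Adipocyte markers, of which 2 were tested as genes and neither passed, summed to 71.4 ± 4.17 against 66.5 ± 7.42 CPM (exact permutation p = 0.314). Erythroid and megakaryocyte markers, with no tested member, summed to 0.564 ± 0.224 against 0.203 ± 0.122 CPM (exact permutation p = 0.0571, adjusted 0.114).

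How 96 genes and 36 lists followed these markers within groups was examined after the data had been seen. The measures were the stromal score and the log2 sum of the 10 endothelial markers under the low-count filter, with 576 relabelings of libraries within groups. In OB the endothelial sum rests on 1 to 20 counts per library, so each relation with it is imprecise. By chance about 1 in 20 genes or lists would reach a permutation p under 0.05 for r or for rho taken alone. Of 91 genes outside the stromal score, 5 had a permutation p under 0.05 for both r and rho with that score, namely CTSK, CTSB, CHI3L1, HLA-DRB1 and SPI1. CTSK was the 1 that passed adjustment, by r and not by rho. The 96 genes adjusted together included stromal markers of the score itself, which follow it by construction. A single gene at the smallest possible p could not pass over 96 genes, so CTSK passed only alongside those markers. SPI1 was imprecise in OB for want of counts. With the endothelial sum 9 genes had a permutation p under 0.05 for both r and rho, and none passed (smallest adjusted permutation p = 0.310 for r and 0.250 for rho). Of these ADGRF1, SOST, VCAM1, NOTCH2 and MT-CO3 had positive r, and ADM, PGF, PLIN2 and SDHB negative r. A single list at the smallest p that 576 relabelings allow adjusts to 0.0625 over 36 lists, so it could not pass alone. Of the lists, 3 reached an unadjusted permutation p under 0.05 for both measures with each score, and none passed adjustment. With the endothelial sum these were basement membrane and integrins, Hippo/YAP targets, and hypoxia and glycolysis. Hippo/YAP targets gave r = 0.833 and rho = 0.905 (permutation p = 0.0312 and 0.0122, adjusted 0.275 and 0.438). Their r without ME replicate 2 and OB replicate 1 was 0.636. The hypoxia list ran opposite to the endothelial sum within groups, although both had higher means in ME. It gave r = −0.726 and rho = −0.762 (permutation p = 0.0104 and 0.0451, adjusted 0.275 and 0.453), and r = −0.833 without the same libraries.

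**Figure D3:**
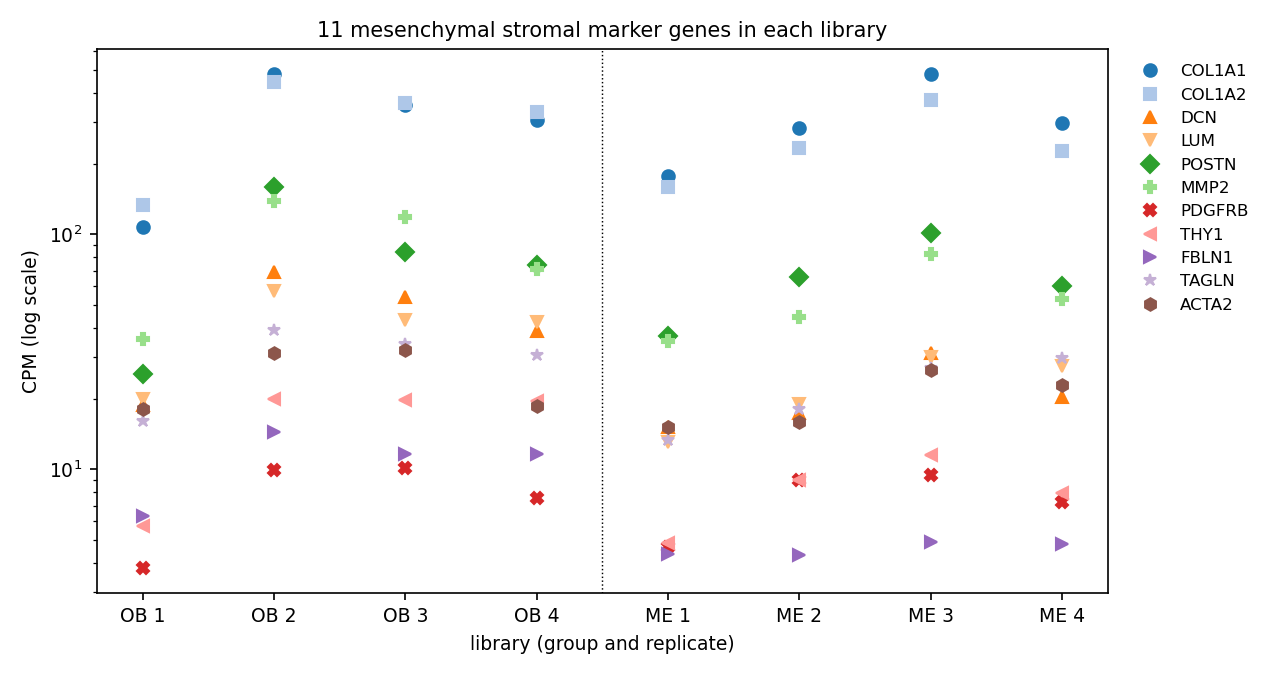
CPM on a log scale (vertical axis) of 11 stromal marker genes in each library (horizontal axis), OB to the left and ME to the right of the dotted line. COL1A1 runs from 107 CPM in OB replicate 1 to 481 CPM in ME replicate 3, and FBLN1 lies between 4.33 and 4.93 CPM in ME and between 6.30 and 14.3 CPM in OB.

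The other lists were not called with all 8 libraries. Adjusted over the list alone, 2 of 20 Hippo/YAP targets were lower, GADD45A and CCN1, a matricellular protein, at 738 ± 105 against 1012 ± 82.7 CPM (camera adjusted p = 0.260). HERPUD1, which takes part in degrading misfolded proteins, was the only lower member among 25 of unfolded protein and integrated stress response, at 149 ± 8.24 against 203 ± 15.3 CPM (0.856). HES1, a Notch-induced repressor, was the only lower member among 12 Notch ligands and targets, at 30.2 ± 4.35 against 45.8 ± 7.50 CPM (0.447). Lysosome and autophagy had 1 of 21 higher, NPC1 at 298 ± 23.1 against 224 ± 41.3 CPM, and 1 lower, CTSB at 75.1 ± 26.8 against 145 ± 55.7 CPM (0.153). Centred by group, CTSB followed the stromal score at r = 0.977 and rho = 0.881 (permutation p = 0.00521 and 0.0139, adjusted 0.0714 and 0.148 over 96 genes). Its r without OB replicate 1 and ME replicate 1 was 0.890. No member passed either adjustment in immediate early genes (19 tested, camera adjusted p = 0.0716), oxidative phosphorylation (nuclear) (26, 0.319), glucocorticoid-induced genes (17, 0.441), NRF2 and oxidative stress (18, 0.563), cholesterol synthesis (22, 0.685), p53 targets (16, 0.852) or heat shock proteins (13, 0.856). Of these, the immediate early list (mean −0.11) was called lower without OB replicate 2 (−0.092, adjusted p = 0.0470), OB replicate 4 (−0.15, adjusted p = 0.0411) or ME replicate 4 (−0.17, adjusted p = 0.000981) and with GC correction (−0.15, adjusted p = 0.00425). Its mean was −0.070 without ME replicate 1. The nuclear oxidative phosphorylation list (mean 0.034) was called higher without OB replicate 4 (0.13, adjusted p = 0.000519) or ME replicate 2 (0.078, adjusted p = 0.0267). Its mean was −0.014 without ME replicate 4, −0.0026 without OB replicate 3 and 0.0037 without OB replicate 2. Cholesterol synthesis (mean −0.063) was called lower without OB replicate 2 (−0.14, adjusted p = 0.0271) and with the stromal covariate (−0.14, adjusted p = 0.0198). Its mean was 0.058 without OB replicate 1. In all, 12 of 36 lists tested were called with a preset correlation, 6 in each direction, and none with an estimated correlation. The sign of the mean, the median or the test differed within 6 lists, all uncalled: fibrillar collagens and matrix, matrix proteases and inhibitors, epithelial-mesenchymal transition, G1/S and DNA replication, TGF-beta targets and haematopoietic markers.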

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

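The tests of stromal RNA left in the sorted cells, of its composition, of dilution by stromal RNA and of the GC-corrected calls over other splits of the libraries were chosen after the results they bear on had been seen. For a single library carrying the stromal or hypoxia mean, and for the relation of interferon-stimulated genes with stromal RNA, the rule for reading the outcome was made more cautious after the values were seen: the first 2 would have been read as excluded and the last as supported under the original rule.

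With 4 libraries per group there are 35 ways to split the 8 libraries. The 2 genes called between ME and OB were matched or exceeded in 2 of the 35 splits, the real 1 included, and the highest other split gave 6 genes, so chance is not excluded for that count. Of the 1087 genes with an unadjusted p under 0.05, as many were found in 3 of 35 splits, the real 1 included, with 1668 in the highest other, so chance is not excluded there either. Of the other alternatives for the same count, the fit corrected for GC trends gave 33 genes in the real split against at most 6 in any other. Only the real 1 of 35 splits reached it, the smallest share possible. The correction was chosen on the real split, whose 33 genes were known before the other splits were run, so chance is not excluded for that count. That count fell to 2, 3, 5 and 2 without ME replicates 1 to 4, to 5 without OB replicate 2 and to 7 without OB replicate 3. The 12 lists called with a preset correlation were reached in 8 of 35 splits, with 18 in the highest other split, so chance is not excluded for the number of lists. The median over the other splits was 6.5 lists, which shows how readily co-varying lists are called at the preset correlation.

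Stromal markers had a mean log2 fold change of −0.43 in ME over OB and were called with the preset correlation only (adjusted p = 0.780 with an estimated correlation). After all libraries were thinned to the smallest total the mean was −0.44. Thinning leaves the expected CPM ratios unchanged, so it covers counting error and the low-count filter only. Other effects that go with the differing library totals are not excluded by it. The presence of stromal RNA itself fits: 11 markers rose and fell together over the libraries after centring by group (mean pairwise correlation 0.891), and together they made up 0.0391% to 0.146% of counts. These 11 were taken from the 15 tested members of the list without a rule fixed beforehand. Their correlation was not computed with libraries left out. A smaller amount of RNA from stromal cells of 1 composition would move the 11 markers alike if the cancer cells expressed none of them. The markers moved apart: the SD of their ME minus OB differences was 0.42 against at most 0.33 in other splits. Only the real 1 of 35 splits reached it, the smallest share possible. Expression of some markers by the cancer cells could set them apart too, so stromal RNA of 1 composition is not excluded. Whether a single library carries the mean stays open, as it was −0.22 without OB replicate 2. A difference in the stromal cells present, as the design would give, stays open as well and was not tested further.

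Hypoxia and glycolysis genes had a mean log2 fold change of 0.19 and were called higher in ME with the preset correlation only (adjusted p = 0.706 with an estimated correlation, 0.594 by fry). Among 10000 lists matched on GC content, transcript length and abundance, the mean stood at percentile 100, above the highest matched mean of 0.18, and after thinning it was 0.18. The matched lists averaged 0.033. Their genes were drawn 1 by 1 and so lack the co-variation of this list (estimated inter-gene correlation 0.604). Their spread is therefore too narrow for the percentile to exclude chance or the matched properties. Less dilution of cancer cell RNA by stromal RNA could not be judged from the epithelial markers. Their mean plus 2 standard errors, taken over 13 genes, was 0.0992. TMM scaling held the median log2 fold change of all genes at −0.002, so these markers would lie near 0 with or without dilution. Without OB replicate 4 their mean was 0.073. A single library is not excluded, as the hypoxia mean was 0.11 without OB replicate 4, and OB replicate 1 lay above all ME libraries. A response of the cancer cells to the added cells, or to oxygen use in the tissue, remains open and was not tested, and the label permutation of the list mean gave an exact p of 0.286.

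Interferon-stimulated genes had a mean log2 fold change of −0.15 and were called lower in ME with the preset correlation only (adjusted p = 0.830 with an estimated correlation, 0.797 by fry), with none of 25 members past the threshold when adjusted over the list alone. A single library may carry this difference, since without ME replicate 1 the mean was −0.042 and without OB replicate 3 it was −0.063. Over the 8 libraries, centred by group, the interferon score followed the stromal score at r = 0.633 and rho = 0.714 (permutation p = 0.0816 and 0.0747, adjusted 0.326 and 0.299 over 4 relations), but r was 0.015 without OB replicate 1 and ME replicate 1, so the relation rests on those libraries. Stromal RNA as a source therefore cannot be told apart from other explanations with so few libraries, and no biological explanation was tested.

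Single libraries stood apart from the rest of their group by Dixon's criterion in 21 of 280 groups of 4 tested, where chance gives about 1 in 20, or 14. ME replicate 1 had 16438 detected genes against 16798 to 16871 in the other ME libraries, and it was lowest for IFI6 (236 against 338 to 348 CPM), IGFBP4 (1378 against 1581 to 1618 CPM), SPP1 (7.03 against 8.45 to 8.73 CPM) and SPOCK1 (3.97 against 6.04 to 6.29 CPM) and highest for IGFBP3 (173 against 119 to 126 CPM). OB replicate 1 was low for the mean log2 CPM of matrix proteases and inhibitors (5.31 against 5.89 to 5.91), for THY1 (5.73 against 19.5 to 19.9 CPM) and for summed osteoblast markers (85.8 against 102 to 103 CPM). In OB replicate 4 the mean log2 CPM of ribosomal proteins was 8.97 against 8.51 to 8.55, and that of nuclear oxidative phosphorylation genes 8.01 against 7.66 to 7.71, and RPS11 stood at 322 against 224 to 236 CPM and RPLP0 at 1160.0 against 823 to 865 CPM. OB replicate 3 was high for COL4A2 (91.2 against 68.7 to 71.8 CPM), ROBO4 (41.5 against 30.7 to 32.3 CPM) and CSF3 (14.9 against 13.3 to 13.4 CPM). ME replicate 4 was high for PECAM1 (9.0 against 6.12 to 6.52 CPM) and low for NRP2 (50.1 against 53.3 to 53.8 CPM), and ME replicate 2 was low for PGF (10.1 against 11.1 to 11.3 CPM) and high for CD44 (1176 against 1025 to 1041 CPM). SPI1 stood at 0.622 CPM in ME replicate 3 against 0.310 to 0.329 CPM in the other ME libraries.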

How the results depend on the processing

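The GC correction, thinning, the stromal covariate, the permutation of list means and the threshold of 0.1 were chosen after the data were examined. Against 2 genes in the reported fit (1 higher, 1 lower in ME), RLE, upper-quartile and total-count scaling each gave the same 2, and the median log2 fold change of all genes stayed within 0.033 of 0 in every fit. DESeq2 called 147 genes (70 higher, 77 lower), no low-count filter 44 (27 and 17), limma-voom 4 (3 and 1), a minimum mean of 5 CPM 5 (4 and 1), leaving out mitochondrial and ribosomal protein genes 5 (4 and 1), thinning 4 (2 and 2), the stromal covariate 3 (2 and 1) and a threshold of 0.1 gave 34 (19 and 15). A minimum absolute log2 fold change of 1 left 1 (0 and 1), by its construction, without TGFBI. Apart from that setting, each fit on all 8 libraries called both ADGRF1 and TGFBI. The GC correction called 33 genes (21 and 12), while the same 12993 genes without it gave 2. With 1 library left out, calls ranged from 1 to 17 (0 to 16 higher, 1 to 3 lower), the most without OB replicate 3. ADGRF1 passed in each of these fits (highest adjusted p = 0.0348, without ME replicate 1), and TGFBI in 4 of 8. Except for the construction named, the cause of these moves was not tested. In the reported fit, with 2 genes, the share of calls in each direction rests on too few genes to compare.

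The replicate number as a block gave 15 genes (6 and 9), both original genes among them, and the same 12 lists. With the GC correction the replicate block gave 45 genes (24 and 21). The samples were not treated as paired because the labels state no block or batch, but a batch shared by number is not excluded. Each of the 8 libraries correlated best in its deviations with its own number, although weakly (0.034 to 0.082). Correlations with GC content had the same sign within each number, such as −0.431 in OB and −0.138 in ME for replicate 2. Replicate 4 was highest in both groups for the mean log2 CPM of ribosomal proteins (8.97 in OB, 8.90 in ME). The same held for nuclear oxidative phosphorylation genes (8.01 and 7.94).

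Of the 12 lists, 0 held with camera at an estimated correlation and 0 by directional fry. The estimated correlation was −0.037 for endothelial markers and 0.0045 for growth factor receptors and ligands, below the preset 0.01. A higher correlation therefore does not account for the loss of those calls. A call lost at an estimated correlation thus does not by itself show that the members of a list vary together. The permutation of list means could not pass in this design and is left aside. Scaling left the same 12, thinning 9 of them (the endothelial list was then too small to test), the stromal covariate 6 of them among 8 called, and the GC correction all 12 among 14. Leaving out 1 library gave 5 to 15 lists, fewest without OB replicate 3, and hypoxia and glycolysis, endothelial markers, and MHC and antigen presentation were called in all 8 of these fits. The mitochondrially encoded list ranged from a mean of −0.036 without OB replicate 1 to 0.31 without OB replicate 2. With the stromal covariate, built from 11 of its own members, the stromal list turned to 0.11 and COL1A1 to 0.76 (adjusted p = 0.0137).

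The permutation tests of summed markers of other cells can hardly pass at this size, so their 0 lists under each alternative show no stability. The ratio of library totals was 1.80 on filtered rows too. Named genes gave 1948 other values with an unchanged call, 135 that newly passed, 4 that no longer passed (TGFBI) and 1, COL1A1, that both turned and passed. Lists gave 539, 17 and 53, and 2 in which a called list turned without a call, the mitochondrial and stromal values named above. Counted whether called or not, the sign changed in 21 values of 4 genes, none of them called in the reported fit: COL1A1 (9), IL11 (5), MKI67 (5) and IL6 (2), whose reported log2 fold changes were within 0.091 of 0. Among lists camera's direction changed in 34 values, and the sign of the mean in 49 values of 15 lists. Of these, 3 lists were called in the reported fit: basement membrane and integrins (5), mitochondrially encoded genes (1) and mesenchymal stromal markers (1). OB replicate 2, with 9.13 M counts, limits what can be seen among low-expressed genes.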

Other observations

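All values in this part were looked for after the comparison of ME with OB had been seen.

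Transcripts of endothelial markers under the low-count filter were present in trace amounts and summed higher in ME. The 10 members of the endothelial list under the low-count filter summed to 50, 193, 112 and 54 counts in ME replicates 1 to 4 and to 1, 11, 14 and 20 counts in OB replicates 1 to 4, or 2.74 ± 1.54 against 0.673 ± 0.539 CPM (SD, n = 4 each, exact permutation p = 0.0286, the smallest possible). VWF, stored by endothelial cells for clotting, had 3, 76, 15 and 0 counts in the ME libraries and 1 count over all OB libraries. TIE1, an endothelial receptor kinase, had 5, 20, 13 and 13 counts against a single count in OB, and FLT1, a VEGF receptor, 29, 21, 3 and 5 against a single count. By mean CPM 8 of the 10 were higher in ME, while ERG, an endothelial transcription factor, was at 0.0126 CPM in ME and 0.174 CPM in OB and CLDN5, a tight junction protein, at 0.105 and 0.114 CPM.

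Ratios of stromal transcripts to COL1A1 differed between the groups as well. Relative to COL1A1, 7 of 10 other stromal markers were lower in ME in all libraries, with log2 ratios that did not overlap (exact permutation p = 0.0286 each, adjusted 0.0408 over the 10 ratios), although ratios with a shared denominator are not independent. All 10 had a lower mean log2 ratio in ME, by −0.086 for PDGFRB to −1.28 for FBLN1. COL1A1, chosen after its values were seen, thus had the highest change of the 11 markers, which fixes that shared direction. These ratios do not tell a change in COL1A1 from a change in the other markers. The log2 ratio of DCN to COL1A1 was −3.85 ± 0.213 in ME and −2.75 ± 0.194 in OB (SD, n = 4 each), that of THY1 −5.19 ± 0.173 and −4.24 ± 0.257, that of FBLN1 −5.97 ± 0.519 and −4.70 ± 0.432, and that of LUM −3.77 ± 0.249 and −2.85 ± 0.292. For PDGFRB, TAGLN and ACTA2 the ratio did not pass the threshold (adjusted exact permutation p = 0.686, 0.107 and 0.444). The cancer cells themselves may express some of these genes, and the stromal covariate (COL1A1 at 0.76) did not separate that possibility.

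The genes ranked 3 to 12 by p, none of which passed, were named after their values were seen. Higher in ME were NRP2 (adjusted p = 0.0551), DHRS3, which reduces retinal, at 6.12 ± 0.687 against 2.14 ± 0.449 CPM (log2 fold change 1.49, SE 0.24, adjusted p = 0.0551), SERPINA3, a protease inhibitor, at 9.45 ± 2.74 against 2.31 ± 1.05 CPM (1.96, SE 0.32, adjusted p = 0.0551) and TCN1, a vitamin B12 carrier, at 14.7 ± 1.42 against 5.52 ± 2.23 CPM (1.43, SE 0.24, adjusted p = 0.0612). PSG11 (1.88, adjusted p = 0.0615), ARHGEF6 (1.34, adjusted p = 0.0731) and NAV1 (0.63, adjusted p = 0.0755) were higher as well. Lower in ME were VIPR1 (−1.87, adjusted p = 0.0718), SPNS2 (−1.25, adjusted p = 0.0755) and SPOCK1, a matrix proteoglycan, at 5.62 ± 1.11 against 13.8 ± 4.34 CPM (−1.28, adjusted p = 0.0731).

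Libraries differed in how their values followed GC content. Across genes, which are not independent replicates, the Spearman correlation of a library's deviation with GC content ran from −0.431 in OB replicate 2 to 0.440 in ME replicate 4, and the median of the tenth of genes richest in GC (above 61.3%) minus that of the poorest (under 38.5%) was −0.46 log2 units in the former and 0.38 in the latter. The trends showed no detectable difference between the groups (exact permutation p = 0.371), but the log2 fold change of ME over OB followed GC content at a Spearman correlation of 0.248 across genes, and 0.016 after correction. Removing the trends lowered the common dispersion from 0.0307 to 0.0254 and raised the calls from 2 to 33. Of the 33, 30 had an adjusted p under 0.1 before the correction, and the 33 included NRP2, ITGA5, ITGB3, TIMP3, EPAS1, SERPINA3, TCN1 and DHRS3 as higher in ME and FBLN1, SOST, CDH11, HERPUD1, CHI3L1 and SPOCK1 as lower. The list means for hypoxia and glycolysis, stromal markers and interferon-stimulated genes were 0.18, −0.40 and −0.16 after correction. With 1 library left out as well, between 2 and 30 genes were called, the fewest without ME replicate 1 or ME replicate 4 (2 each), then 3 without ME replicate 2, 5 without OB replicate 2 or ME replicate 3, 7 without OB replicate 3, 23 without OB replicate 4 and 30 without OB replicate 1. Fewer libraries also lower the power of the fit, and that was not separated from a dependence on particular libraries. On counts simulated with these trends, 140 of 190 changed genes were recovered with the correction and 132 without. The simulated dispersions came from the uncorrected fit and already held the variance of the trends. That simulation may therefore understate the gain and is no measure of the rise from 2 to 33 calls.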
